A study of Homo sapiens
Mus musculus with 4 samples.

How the data were processed

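The data are 10x Genomics version 3 single-cell RNA-seq libraries of what the labels name as luciferase-positive LOUCY cells, a human T-cell acute lymphoblastic leukaemia line, grown in 2 female NSG mice, a severely immunodeficient strain. One mouse received vehicle and the other ABT-199 (venetoclax, an oral BCL2 inhibitor) at 50 mg/kg daily for 11 days, and bone marrow and spleen of each were dissociated on the last day, per the labels' protocols. The sample titles call the arms control and relapse. The relapse arm was read as the ABT-199 arm, since the protocols name only vehicle and ABT-199. Each of the 4 groups held 1 library, so arm and mouse were the same factor, and no test, p-value or replicate spread is given.

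The authors deposited filtered feature-barcode matrices of UMI counts, whole numbers per gene and barcode and not normalized. Per the submitters' processing notes, Cell Ranger 3.0.2 and the builds hg19 and mm10 were used. The files list 57905 human and 54232 mouse features side by side. Gene names were taken from the files. Genome coordinates were not used here.

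A barcode was called human or mouse where 90% or more of its UMIs were of that genome, and mixed otherwise. Human cells were kept with 500 or more human genes and mouse cells with 200 or more mouse genes, both with a mitochondrial share of 20% or less. UMIs were summed per library over human cells and divided by the total human UMIs to give CPM (counts scaled to a fixed total). Ratios of CPM carry exact conditional binomial 95% intervals and shares of cells exact Clopper-Pearson 95% intervals. For a share of 0 the limit given is 3 counts of the total. These cover counting error only and leave out differences between mice, dissections and library preparations. Log2 ratios used a pseudocount of 1 CPM. The interval was tested on simulated counts for the control spleen against control marrow comparison (5951 genes), where it held the true value for 96% of 50 genes simulated 2-fold higher, 92% of 50 simulated 2-fold lower and 95.7% of 5751 unchanged genes. These counts were independent Poisson draws, the model that the interval assumes. The test therefore checks the computation only, and differences between cells of a library were not simulated.

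Named genes were, per comparison, the 12 highest and 12 lowest log2 ratios among genes with 100 or more UMIs and 20 or more CPM in the higher library, the 10 highest and 10 lowest that moved 1.5-fold or more the same way in both organs or arms, the detected BCL2 family, and up to 4 members per gene list with the largest ratios. Mitochondrial, ribosomal protein and clone-named genes and the genes that mark a donor's sex were left out of that naming, and 1 gene that the rule named is not reported here. A list is described by its median log2 ratio, by how many members with 20 or more UMIs differed 1.5-fold, and by the percentile of its median among 10000 random lists of the same size and similar expression. The comparisons, lists, naming rule, cell type markers and the other settings to try were fixed before the data were examined.

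For cell cycle phases and clusters, human cells of 1400 or more UMIs were thinned to 1400 UMIs and shallower cells were left out. Leiden clustering (scanpy 1.11.5, igraph 0.11.9, 2000 variable genes, 30 components, 15 neighbours) used 4913 cells per library at resolution 0.5 for human cells, and all 19568 mouse cells at resolution 1. Scrublet marked 0 cells in 3 of the 4 libraries and therefore had not worked, so doublets were kept. Phase calls without the marked cells were made, but the expression comparisons were not run without them.

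The human populations were defined after the clusters had been seen. Clustering was repeated without 1319 of 14540 genes that differed 1.5-fold between arms or belonged to the immature T-cell list. Of the resulting clusters, the one with the highest share of UMIs from the immature T-cell list was taken as population 2. All other clustered cells gave the profile of population 1. Each human cell was then given a mixing fraction between these profiles by maximum likelihood over 1069 genes that differed 4-fold between them. These were drawn from all genes, including those left out of the clustering. Cells under 0.1 were called population 1 and cells at 0.8 or above population 2, limits set after seeing the distribution of fractions. The rule that named mouse classes, 3 or more own markers among a cluster's top 50 genes and none of another class ahead in the top 10, was also set after the cluster genes had been seen, although the markers themselves were not. Clusters that missed it were left unnamed, and their summed share is given. Alternatives covered the species limit, cell filters, scaling, pseudocount, gene filter, depth, phase, thinning and resolution. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.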

Results

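Single-cell transcriptomes were collected from bone marrow and spleen of a vehicle-treated and an ABT-199-treated mouse carrying, per the labels, LOUCY leukaemia, to ask how residual leukaemic cells in the spleen compare with those in the marrow after BCL2 inhibition. There was 1 library per group. The files held 22818 barcodes in the control marrow-labelled library, 14932 in the control spleen-labelled, 22152 in the relapse marrow-labelled and 21466 in the relapse spleen-labelled library, with 80281571, 67416338, 60826748 and 70132498 UMIs. After filtering, 7640, 11545, 5288 and 11610 human cells remained, with median depths of 4303, 4568, 3588 and 3697 UMIs. Mouse genes of bone cells and of spleen macrophages went against the organ labels in part of the tests given in the closing section. Libraries are therefore named by their labels, and every organ direction below is one between labels.

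Human cells made up most cells of both spleen-labelled libraries and fewer of the marrow-labelled ones. Their share was 92.6% (95% interval 92.1 to 93.1) in the control spleen-labelled and 77.4% (76.7 to 78.1) in the relapse spleen-labelled library. In the marrow-labelled libraries it was 45.6% (44.8 to 46.3) in the control and 46.3% (45.4 to 47.3) in the relapse arm. Barcodes of mixed species, left out of these shares, were 15.4%, 2.56%, 36.1% and 15.9% of the control marrow-, control spleen-, relapse marrow- and relapse spleen-labelled libraries. Mixed barcodes, depth and free RNA can set these shares, and stricter cell filters gave 36.7% and 14.1% for the spleen-labelled and 11.8% and 4.96% for the marrow-labelled libraries.

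The human cells were set against 2 profiles, that of 1 cluster (population 2) and that of all other clusters pooled (population 1). Population 2 was rare in the control and common in the relapse libraries. Clustered without the genes that differed between arms, population 2 held 0.733% (0.514 to 1.01) of 4913 control marrow-labelled cells and 0.244% (0.126 to 0.426) of control spleen-labelled cells, against 30.2% (28.9 to 31.5) and 21.9% (20.8 to 23.1) in the relapse marrow- and spleen-labelled libraries. With a mixing fraction for every human cell, its share was 1.26% (96 cells), 0.572% (66 cells), 32.9% (1742 cells) and 28.2% (3277 cells). Cells between the limits were 0.563%, 0.494%, 4.08% and 6.77%. Population 2 cells were shallower, with medians of 1280 to 2030 UMIs against 4340 to 4890 for population 1. The cluster shares left out cells under 1400 UMIs, a limit near these population 2 medians. Among cells of 2658.5 to 6017 UMIs its share was 0.173%, 0.0149%, 18.7% and 9.55%, so the arms stayed apart while the level depended on depth. The other human cells were not uniform. At resolution 1, a cluster with CCR9 and CD1A among its leading genes held 767, 283, 555 and 302 of 4913 cells, in the same library order. A cluster led by KRT81 held 57, 391, 64 and 193. Whether the organ differences of CD1A and KRT81 given below follow these shares was not tested.

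**Figure D1:**
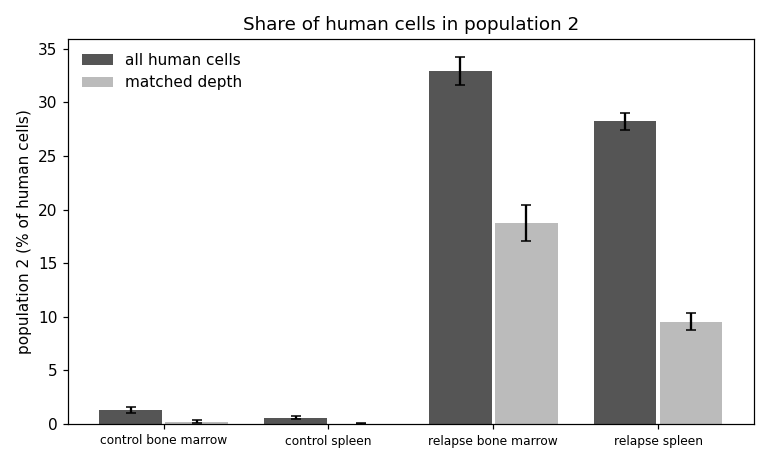
Share of human cells in population 2 (y axis, percent) in the 4 libraries (x axis), over all human cells (dark bars) and cells of matched depth (light bars), with exact 95% intervals for counting error. The relapse libraries stand at 32.9% and 28.2% of all human cells and the control libraries at 1.26% and 0.572%.

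Population 2 carried transcription factors of immature T-cell leukaemia that population 1, which held most control cells, nearly lacked. HHEX stood at 198 CPM (189.6 to 206.9) against 0.257 (0.183 to 0.352), MEF2C at 92.4 against 0.106, HOXA10 at 158.8 against 0.172, HOXA9 at 82.9 against 0.0857 and ERG at 76.8 against 0.350. LYL1 was present in both, at 348 against 34.1 CPM. Of 16 measured immature T-cell genes 14 were higher in population 2, whereas 17 of 26 T-lineage maturation genes were lower. Among these, TCF7, a T-cell transcription factor, stood at 33.2 against 592 CPM and CD1E, a CD1 family gene of cortical thymocytes, at 11.6 against 358. LCK was at 101.2 against 445 and the recombinase RAG1 at 1.07 against 31.8. The BCL2 family also differed. BCL2, the target of ABT-199, was at 40.6 CPM (36.8 to 44.7) in population 2 and 7.14 (6.72 to 7.58) in population 1, MCL1 at 43.0 against 27.6 and the pro-apoptotic PMAIP1 at 143 against 51.1, whereas BCL2L1 was lower, at 34.7 against 57.5. The adhesion receptor CD44 stood at 120.8 against 18.9 CPM. CPM is relative to each population's total UMIs, and population 2 cells held fewer UMIs. These ratios are therefore not ratios of UMIs per cell. Population 2 was chosen as the cluster with the highest UMI share of the immature T-cell list, so the 14 of 16 was largely fixed in advance. The levels describe populations separated partly by the same genes. LOUCY is known as an early T-cell precursor line, so the population that held most control cells is the one that nearly lacks these factors, and sums over all human cells describe mainly that population.

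**Figure D2:**
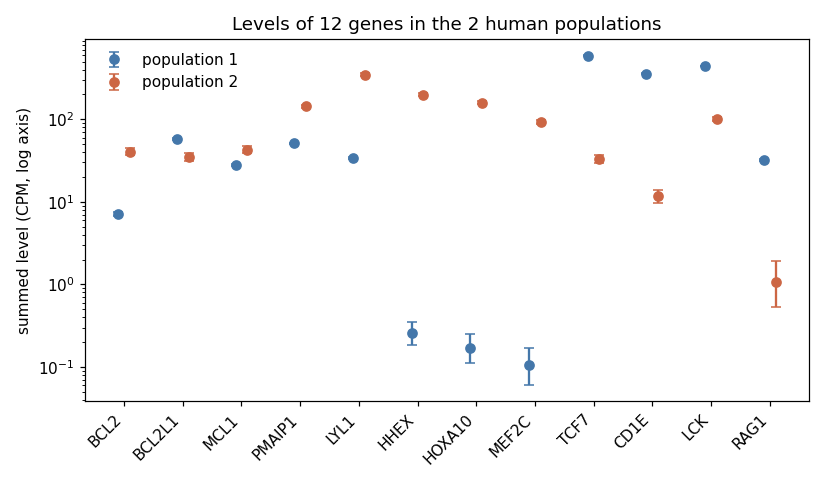
Summed level of 12 genes (y axis, CPM, log axis) in population 1 (blue) and population 2 (orange) over the 4 libraries, with exact 95% intervals for counting error. BCL2 stands at 40.6 CPM in population 2 and 7.14 in population 1, and HHEX at 198 and 0.257.

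Between the arms in the marrow-labelled libraries, summed over all human cells, the relapse library was higher in genes of population 2. PITX1, a homeobox factor, was at 203.8 CPM against 5.15 (ratio 39.6, 34.2 to 46.0), IGLL1, a surrogate light chain, at 241 against 9.36, TRDC, the T-cell receptor delta constant region, at 85.3 against 3.06, and HHEX at 34.0 against 0.922. TSPO, HPGDS, LMO4, SERPINB1 and TSC22D3 were higher at ratios of 32.8, 25.4, 31.1, 26.9 and 22.6, and MEF2C, HOXA10 and ERG at 32.8, 24.7 and 24.9, although MEF2C turned to a log2 ratio of -0.47 with stricter cell filters, which left few cells. Of 15 measured immature T-cell genes 14 were 1.5-fold higher (median log2 ratio 2.40, 100th percentile). BCL2 was higher at 13.1 against 6.16 CPM (ratio 2.13, 1.79 to 2.54), MCL1 at 1.15 (1.04 to 1.27) and BCL2L11 at 1.45 (1.12 to 1.88), while BCL2L1 was level at 0.993 (0.925 to 1.06). The endoplasmic reticulum chaperone HSPA5 was at 314 against 152 CPM, XBP1 at 58.4 against 33.5 and SDF2L1 at 291 against 186, and 6 of 25 ATF4 and unfolded protein response genes were 1.5-fold higher (median 0.28, 100th percentile), as were 3 of 14 heat shock genes (0.09). Of 20 immediate early genes 7 were 1.5-fold higher (median 0.22, 99.65th percentile), and within population 1, 3 of 20 (0.19). GADD45A was 4.31-fold higher, IER3 2.27-fold and RELB 2.42-fold. The relapse library was lower in RAG1 (16.2 against 30.5 CPM), CD1B (60.3 against 108), CD9 (18.8 against 32.7), ARPP21 (42.0 against 68.4) and MYC (44.9 against 66.9). Arm and mouse cannot be told apart in this or the next comparison.

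Within population 1 alone the 95th percentile of the absolute log2 ratio between the same libraries was 0.333, against 0.455 over all cells. Leaving out population 2 removes the cells that its genes define, so part of this drop is fixed by the choice of cells. BCL2 was at 7.63 against 5.94 CPM (ratio 1.28, 1.03 to 1.60), and MCL1 at 0.994 times the control level. HSPA5 (335 against 152 CPM) and IER3 (31.1 against 13.5) differed as much as over all cells. SDF2L1 (316 against 186) and the heat shock genes DNAJB1 (90.8 against 53.5) and HSPH1 (304 against 197) remained higher, and RAG1 (19.2 against 30.8) and SRSF5 (117 against 188) lower. The mouse cells of these libraries shared 2 of these changes. Hsph1 was at 77.0 against 35.5 CPM in conventional dendritic-like and 60.2 against 30.6 in erythroid-like cells. Srsf5 was at 94.3 against 192 in erythroid-like and 164 against 327 in plasmacytoid dendritic-like cells. These mouse values were seen among the 6 highest and 6 lowest genes of a class, and other classes were not read for them. HSPH1 and SRSF5 thus did not differ in the human cells alone, and the cause was not tested. GADD45A and CD44, higher in the sum over all cells, stood at log2 ratios of -0.045 and -0.12 within population 1.

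Between the arms in the spleen-labelled libraries the same genes led. PITX1 was at 123 against 1.67 CPM (ratio 73.8, 60.4 to 91.0), TRDC at 71.3 against 1.16, HHEX at 31.7 against 0.357, HOXA10 at 29.2 against 0.562 and HOXB7 at 21.3 against 0.562. The ratios of TSPO, HPGDS, LMO4, SERPINB1, TSC22D3 and ANXA1 were 51.5, 65.3, 61.3, 72.7, 17.5 and 19.3. Of 15 immature T-cell genes 14 were 1.5-fold higher and 1, CD7, was lower, at 77.1 against 130 CPM (median 2.27, 100th percentile). BCL2 was at 13.7 against 7.05 CPM (ratio 1.94, 1.72 to 2.20), PMAIP1 at 65.8 against 42.9, BCL2L11 at 5.29 against 3.47 and BCL2L1 at 53.6 against 58.2. The relapse library was lower in KRT81 (22.5 against 51.8 CPM), CTSW (13.03 against 29.9), RAG1 (21.9 against 40.6), the pro-apoptotic BIK (16.5 against 23.7) and the cholesterol synthesis genes HMGCS1 (52.5 against 81.6) and MVD (20.4 against 31.9). The cholesterol list had a median of -0.31, below all random lists, with 2 of 22 members 1.5-fold lower. Within population 1, BCL2 was at 8.22 against 7.03 CPM (ratio 1.17, 1.01 to 1.36), the gamma-chain gene TRGC2 at 27.8 against 67.4, CD7 at 71.1 against 130, and the gut-homing receptor CCR9 at 38.7 against 23.2. IGLL1, higher in the sum, was lower within population 1, at a log2 ratio of -1.47.

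The arm differences in the 2 organs correlated at r = 0.640 and rho = 0.279 across 5885 genes, which are not independent replicates. A share-only prediction, in which each organ's change came only from its population 2 share and the other organ's profiles, correlated with the observed ratios at r = 0.828 and rho = 0.537 in the marrow-labelled and r = 0.823 and rho = 0.624 in the spleen-labelled libraries. It gave BCL2 a log2 ratio of 0.69 against 0.98 observed in the marrow-labelled and 0.57 against 0.87 in the spleen-labelled libraries. The prediction is not independent of the values it is set against. Cells were assigned by genes that differed 4-fold between populations pooled over all 4 libraries, and the share came from the predicted library itself. High predicted ratios of those genes were therefore partly fixed in advance, and both organs of an arm come from 1 mouse. Of the spleen minus marrow differences of the arm log2 ratios, the highest were those of MTATP6P1 (1.44), ALYREF (1.29) and ARF5 (1.28), lower in the relapse arm of the marrow-labelled libraries and higher in that of the spleen-labelled ones. The lowest were those of NKG7 (-1.51, counting interval -1.69 to -1.34), TRGC2 (-1.33), MATK (-1.18) and TIMP1 (-1.03), which were higher in the relapse arm of the marrow-labelled libraries and near level or lower in the spleen-labelled ones.

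Between organs in the control arm, the spleen-labelled library was higher in 10 of 22 cholesterol genes and lower in 7 of 25 T-lineage maturation genes, by 1.5-fold or more. HMGCS1, an early enzyme of cholesterol synthesis, was at 81.6 against 29.8 CPM (ratio 2.74, 2.57 to 2.93), LSS at 13.9 against 6.10, DHCR7 at 15.8 against 8.73 and SCD, a fatty acid desaturase, at 39.4 against 18.5. The median of the cholesterol list was 0.51 (100th percentile). RAB25 (23.1 against 8.30 CPM), CTSW (29.9 against 11.3), KRT81 (51.8 against 20.3), NKG7 (32.4 against 14.2), PMEPA1 (80.1 against 38.7) and PDE4D (55.3 against 28.9) were also higher. CD1A (53.1 against 149 CPM), CD1B (41.0 against 108), CD1E (245 against 617), CD4 (13.7 against 30.2) and the NOTCH target DTX1 (2.91 against 10.6) were lower, at a T-lineage list median of -0.18. SMPD3, RHOU, SH3TC1 and the integrin ITGAL were lower at ratios of 0.342, 0.368, 0.453 and 0.494. G2/M genes had a median of -0.30, below all random lists, with UBE2C at 192 against 308 CPM and CDC20 at 94.9 against 148, whereas S phase genes stood at -0.01. The chaperone HSP90AA1 was at 3050 against 4566 CPM, with a heat shock list median of -0.23. BNIP3L (63.8 against 40.5) and PKM (229 against 139) were higher. In the BCL2 family, BCL2 (ratio 1.14, 0.971 to 1.35) and BCL2L1 (1.05, 0.991 to 1.11) did not differ beyond counting error, MCL1 stood at 1.11 (1.03 to 1.21), BIK at 1.42 and PMAIP1 at 0.693. The BCL2 log2 ratio was -0.49 with stricter filters and 2.01 in G1 cells, both on few cells, so its level between these labels depends on the cells chosen.

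Between organs in the relapse arm, the spleen-labelled library was lower in CD1 genes and DTX1, as in the control arm. CD1A was at 42.8 against 110 CPM (ratio 0.388, 0.366 to 0.411), CD1E at 170 against 433, CD1B at 32.6 against 60.3, CD7 at 77.1 against 145 and DTX1 at 1.42 against 16.1. SH3TC1, SMPD3, RHOU and ITGAL were lower at 0.384, 0.442, 0.431 and 0.481 (RHOU reversed to a log2 ratio of 1.22 in G1 cells), and 5 of 24 T-lineage maturation genes were 1.5-fold lower (median -0.29, below all random lists). Some other lists also followed the control arm, such as heat shock genes at -0.27 where the control had -0.23. Cytosolic ribosomal proteins stood at 0.08 where the control had 0.09. G2/M genes did not by their median, at 0.08 (97.4th percentile) where the control had -0.30. Of 54 members 2 were 1.5-fold lower and 0 higher. The share of cells called G2/M was, however, lower in the spleen-labelled library of both arms. It was 70.0% against 79.9% in the control and 72.9% against 77.5% in the relapse arm. The median alone therefore does not show that the organ difference was absent in the relapse arm. Cholesterol genes stood at 0.13 with 2 of 22 members 1.5-fold higher, less than the 0.51 of the control. Within population 1 they stood at 0.22 (98.04th percentile), and within population 2 at -0.29. HSPA5 (188 against 314 CPM) and HSP90AA1 (2708 against 4385) were lower. Higher were NDST3 (34.7 against 16.9 CPM), the phosphodiesterase PDE4D (53.5 against 26.4), MYC (86.8 against 44.9), CYB5D2 (32.8 against 17.0), FBXO32 (20.9 against 11.0 CPM, but at a log2 ratio of -0.034 with stricter filters), the p53 target CCNG1 (51.6 against 30.2) and the hypoxia-response genes BNIP3L (74.8 against 46.2) and PDK1 (11.0 against 5.52). BCL2 (ratio 1.04, 0.909 to 1.20), MCL1 (1.08, 0.984 to 1.18) and BCL2L1 (0.971, 0.908 to 1.04) did not differ between the organ labels beyond counting error. Across 5831 genes the organ differences of the 2 arms correlated at r = 0.415 and rho = 0.343. Within population 2, the spleen-labelled library was higher in DUSP6, a MAP kinase phosphatase (92.6 against 37.1 CPM), SHISA2 (34.3 against 12.9), SBF2 (103 against 46.0) and the pro-apoptotic BAX (ratio 1.35, 1.23 to 1.48), and lower in CPA3 (11.8 against 25.8), NDUFS7 (148 against 270) and ICAM2 (56.8 against 93.9). In these cells 9 of 21 p53 target genes were 1.5-fold higher (median 0.40, 100th percentile). CD1A and RHOU, lower over all cells, were at log2 ratios of 0.14 and 0.016 within population 2.

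Phase calls placed 98.2%, 91.6%, 96.8% and 94.7% of thinned human cells in S or G2/M in the control marrow-, control spleen-, relapse marrow- and relapse spleen-labelled libraries, with 299, 127, 375 and 1143 shallower cells left out and 1.31% to 3.68% of cells near a limit. Nearly all cells met the call and free RNA can enter it, so no difference in cycling was read from it. Without thinning the shares are given with the alternatives. Summed G2/M genes stood at 12620, 10300, 11200 and 11140 CPM and S phase genes at 5500, 5276, 5015 and 5359 CPM.

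The mouse cells were largely myeloid and erythroid where a class could be named. Neutrophil-like cells were 7.55% of mouse cells (7.02 to 8.11) in the control marrow-labelled, 25.4% (22.6 to 28.3) in the control spleen-labelled, 11.2% (10.4 to 11.97) in the relapse marrow-labelled and 43.0% (41.3 to 44.7) in the relapse spleen-labelled library. Monocyte-like cells were 4.50%, 18.5%, 6.17% and 19.2% in the same order, and granulocyte-monocyte progenitor-like cells 0.887%, 6.07%, 0.784% and 6.07%. Erythroid-like cells were 18.0%, 1.63%, 11.6% and 3.68%, conventional dendritic-like cells 11.5%, 15.7%, 12.5% and 4.98%, plasmacytoid dendritic-like cells 1.73%, 2.71%, 3.84% and 2.18%, and basophil- or mast-like cells 3.96%, 6.72%, 2.99% and 9.46%. The 1 cluster named macrophage-like (Sema6d, Fcna, Mertk) held 6.85% and 5.04% of the marrow-labelled libraries and 0 of 923 and 0 of 3393 spleen-labelled cells, which allows shares of that type of up to 0.325% and 0.0884%. An unnamed cluster with other macrophage genes (Gpnmb, Ccl8, C3ar1) lay in the spleen-labelled libraries and is given in the closing section. Unnamed cluster 2, led by the macrophage genes Cd5l, C1qb and C1qc, held 334 and 153 marrow-labelled against 0 and 1 spleen-labelled cells. The macrophage-like shares and limits therefore do not cover all cells with macrophage genes. Stromal cells (Col1a1, Ibsp) were 7 and 5 of the spleen-labelled and 0 of 9127 and 0 of 6125 marrow-labelled cells. At resolution 0.5 they were 107 and 109 of the spleen-labelled cells, as many as this and the unnamed cluster together, and with the 95% limit no cluster was named stromal. Clusters left unnamed held 45.04%, 22.5%, 46.0% and 11.3%. Among them cluster 11 (Ace, Cd300e, Nr4a1), which has genes of the monocyte marker list, held 6.84%, 6.83%, 8.90% and 3.01%. The monocyte-like shares therefore may not cover all monocytes. Cluster 6 (Ppbp, Pf4, Itga2b), led by megakaryocyte or platelet genes, held 5.94%, 2.28%, 8.42% and 1.83%. The control spleen-labelled library rests on 923 mouse cells, and with a minimum of 500 mouse genes the neutrophil-like shares were 5.15%, 10.7%, 7.26% and 27.3% and the granulocyte-monocyte progenitor-like shares 5.29%, 13.5%, 3.27% and 17.2%. With the 95% species limit the progenitor shares of the spleen-labelled libraries parted, at 8.38% and 14.7%, and the monocyte-like shares of the marrow-labelled ones changed order, at 9.70% in the control and 6.04% in the relapse arm. The neutrophil-like shares of the marrow-labelled libraries changed order too, with the relapse share at 6.91%, below the control. At resolution 0.5 erythroid-like cells were 28.9% of the control marrow-labelled library.

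**Figure D3:**
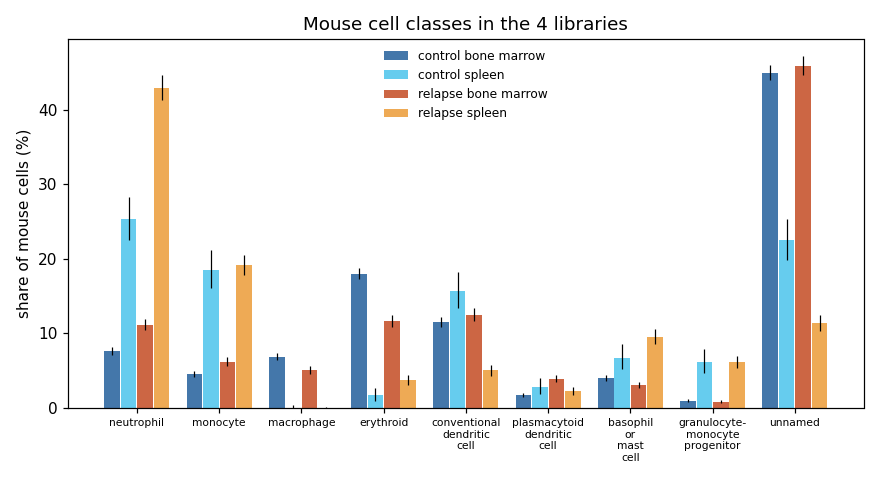
Share of mouse cells (y axis, percent) in each mouse class (x axis) for the 4 libraries, with exact 95% intervals for counting error. Neutrophil-like cells stand at 25.4% and 43.0% in the spleen-labelled and 7.55% and 11.2% in the marrow-labelled libraries.

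In monocytes and neutrophils the mouse interferon-stimulated genes stood higher in the relapse arm of the marrow-labelled libraries and lower in that of the spleen-labelled ones. In marrow-labelled macrophages 8 of 9 measured members were 1.5-fold higher (median log2 ratio 0.78), in monocytes 6 of 10 (0.69), in plasmacytoid dendritic cells 5 of 7 (0.87) in neutrophils 3 of 10 (0.47), in conventional dendritic cells 4 of 11 (0.28), in basophils or mast cells 2 of 5 (0.14) and in erythroid cells 1 of 8 (0.018). In spleen-labelled neutrophils, of which cluster 14 held most in the control (149 of 234 cells) and cluster 15 in the relapse library (788 of 1459), 9 of 11 were 1.5-fold lower (-1.38), in monocytes 6 of 10 (-0.95) and in granulocyte-monocyte progenitors 4 of 5 (-1.10), with Irf7 at 72.4 against 219 CPM and Isg15 at 69.2 against 155 in monocytes. Spleen-labelled conventional dendritic cells stood at 0.29 and basophils or mast cells at -0.52, each over 2 measured members. Iron and heme recycling genes had a median of -0.24 in marrow-labelled macrophages, efferocytosis genes -0.14, inflammatory genes 0.10 and niche cytokines -0.57 over 3 measured members. Neutrophil genes appeared in other classes of the relapse libraries, with S100a9 at 2828 against 31.6 CPM in spleen-labelled basophils or mast cells, and hemoglobin genes did so in spleen-labelled neutrophils, with Hbb-bs at 4780 against 49.1 CPM.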

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

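The tests of bone genes without Acp5, of spleen genes without Treml4 and of intermediate mixing fractions were chosen after the result had been seen, and none of the differences between organs below was tested, since each rests on 1 library per group.

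Mouse interferon-stimulated genes of monocytes and neutrophils moved in opposite directions with arm in the organs. The spleen minus marrow difference of the median log2 ratio was -1.64 in monocytes and -1.84 in neutrophils, which in the spleen-labelled libraries came mostly from cluster 14 in the control (149 of 234 cells) and cluster 15 in the relapse arm (788 of 1459). Among the 12 highest and 12 lowest differences of human genes, those with opposite directions and a change of 1.3-fold or more in both organs, a limit set after the values had been seen, were MTATP6P1 (spleen minus marrow difference of log2 ratios 1.44), ALYREF (1.29), ARF5 (1.28), NDUFB3 (1.05), SEC61G (0.99), PPP4C (0.92) and CD79A (-1.01). Of 5885 genes 1 moved 1.5-fold or more in opposite directions. MTATP6P1 is a nuclear copy of a mitochondrial gene and shares reads with it. In data outside the comparisons, mixed-species barcodes were 36.1% of the relapse marrow-labelled and 15.9% of the relapse spleen-labelled library, above the 15.4% and 2.56% of the control libraries, and 55.5% and 42.7% of the mixed barcodes in the relapse libraries held under 1000 UMIs. Human barcodes left out for a mitochondrial share above 20% were 27.9% and 19.1% in the relapse marrow- and spleen-labelled libraries, against 12.8% and 14.8% in the controls.

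A human population with early T-cell genes was rare in the control and common in the relapse libraries. The lower depth of these cells was argued against as the whole cause: at matched depth the spleen-labelled relapse share was 639 times the control share, a ratio that rests on 1 control cell. A graded change of 1 population was argued against only on a linear scale, by few intermediate cells. At most 2.66% of a relapse library had a mixing fraction of 0.3 to 0.7, and 4.08% and 6.77% lay between 0.1 and 0.8. The fraction mixes the summed profiles linearly. For genes such as HHEX (198 against 0.257 CPM) a cell halfway on the log scale would lie near the population 1 end. A change graded on the log scale was therefore left open. The correlation of its control with its relapse cells (r = 0.938 across 7000 genes) decides nothing, since the control cells were picked by their mixing fraction toward that profile. A selection under ABT-199 and 2 human cell stocks growing at different rates in the 2 mice cannot be told apart, because each arm is 1 mouse, and whether both populations are the named line was not tested.

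Mouse genes of bone cells and spleen macrophages lay opposite to the organ labels. An unnamed cluster led by Gpnmb, Ctsk, Ccl8, Atp6v0d2 and C3ar1, genes known from osteoclasts and macrophages, held 100 and 104 cells of the spleen-labelled libraries and 0 and 1 of the marrow-labelled ones. Stromal cells with Col1a1 and Ibsp were 7 and 5 against 0 and 0. The macrophage cluster (625 and 309 cells) and a cluster of pancreatic enzymes (88 and 185 cells) came from the marrow-labelled libraries and held 0 spleen-labelled cells. Unnamed cluster 2, led by Cd5l, C1qb and C1qc, held 334 and 153 marrow-labelled against 0 and 1 spleen-labelled cells. An exchange of labels in both arms failed its planned test on 12 further bone genes: their spleen-to-marrow ratio was 3.75 (3.46 to 4.07) in the control but 0.804 (0.728 to 0.888) in the relapse arm, where 3 or more had been required of both. Acp5, at 840 CPM in the macrophage cluster too, gave 96.8% of those UMIs, and without it the ratio was 26.1 (17.9 to 38.6) in the control arm, in line with an exchange there, and 1.43 (0.792 to 2.52) in the relapse arm, which leaves that arm open on 20 and 39 UMIs, although the 5 bone genes that had raised the pattern stood at 98.5 against 1.03 CPM there (Ibsp at 31 against 0 UMIs). The 12 further spleen genes had ratios of 0.437 and 0.329, short of the required 3-fold in the control arm. They rest on Treml4 (605 of 635 marrow-labelled and 17 of 21 spleen-labelled control UMIs). Without it the ratios were 1.76 (0.451 to 4.998) and 0.349 (0.0898 to 0.985) and decide nothing. Tissue picked up at dissection of the marrow-labelled samples was predicted to leave the 12 bone genes at 1 or less in both arms. The control ratio of 3.75 went against this in that arm and the relapse ratio of 0.804 did not, so the test could not decide. Pancreatic enzyme genes not looked at before, without Cela1, stood 26.35 and 129.2 times higher in the marrow-labelled control and relapse libraries. They had no part in these tests. All groups were kept as labelled.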

How the results depend on the processing

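Population 1 alone, population 2 alone, removal of the cells richest in UMIs, clusters without arm-dependent genes and the mixing fraction were chosen after the result had been seen. No paired analysis was possible because no result came from a test. A fit of organ blocked by mouse was not made, since its only error term would be the difference between the arms' organ effects. Without Scrublet doublets, which were marked in 1 library, the S or G2/M share of the relapse marrow-labelled library was 96.7% of 4622 cells, and the expression comparisons were not run. The cause of each change was not tested, except that the stricter filters kept 940, 395, 270 and 387 human cells of the control marrow-, control spleen-, relapse marrow- and relapse spleen-labelled libraries, and G1 cells were 129, 956, 155 and 555, so both rest on few cells. Gene list medians moved by 0.25 or less on the log2 scale in 100 of 100 values under each species limit. They did so in 96 of 100 with population 1 alone, 83 of 100 with stricter filters and 72 of 100 in G1 cells. Many medians were themselves under 0.25 in size and could fall to 0 or change sign within that limit. These counts therefore do not measure whether a list kept its direction. Between marrow-labelled arms the T-lineage maturation median went from -0.24 to -0.02 within population 1, and the hypoxia-response median from 0.09 to -0.13. The immature T-cell list, at 2.40 and 2.27 between marrow- and spleen-labelled arms, fell within population 1 to 0.07 over 4 measured members and 0.30 over 7. Of 28 mouse class shares, 19 moved with 500 mouse genes, 21 with the 95% limit, and 7 of 24 with resolution 0.5.

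The BCL2 log2 ratio of the control organs was -0.49 with stricter filters and 2.01 in G1 cells. The relapse to control BCL2 log2 ratio in marrow-labelled libraries was 0.41 with stricter filters, 0.70 with a pseudocount of 5 CPM, 3.90 in G1 cells and 0.31 in population 1, and in spleen-labelled libraries 0.77 with median of ratios size factors, 1.25 as a mean of per-cell CPM, 0.63 with a pseudocount of 5 CPM and 0.20 in population 1. Between the relapse organs it was -0.90 in G1 cells and -0.20 at matched depth. Directions reversed with stricter filters for HRK (-0.25), MEF2C (-0.47) and GADD45A (-0.21) between arms in marrow-labelled libraries and for FBXO32 (-0.034) between relapse organs. In G1 cells they did so for MVD (0.13) between spleen-labelled arms and for RHOU (1.22) and HOXA10 (-0.048, against 0.61 over all cells) between relapse organs, and the median of the anti-apoptotic BCL2 family fell to 0 between marrow-labelled arms. Within population 1 they did so for GADD45A (-0.045) and CD44 (-0.12) between marrow-labelled arms, with HOXA10 at 0, and for IGLL1 (-1.47) between spleen-labelled arms, and within population 2 for CD1A (0.14) and RHOU (0.016) between relapse organs.

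The human cell share was 46.8%, 38.9% and 72.6% in the control marrow-, relapse marrow- and relapse spleen-labelled libraries with the 80% limit, and 47.5%, 94.2%, 60.3% and 88.9% in the control marrow-, control spleen-, relapse marrow- and relapse spleen-labelled libraries with the 95% limit. Without cell filters it was 93.2%, 52.4% and 80.5% in the control spleen-, relapse marrow- and relapse spleen-labelled libraries, and with stricter filters 11.8%, 36.7%, 4.96% and 14.1% in the order of all 4. The S or G2/M share was 98.8%, 93.9%, 98.0% and 96.0% without thinning and 97.2%, 95.4% and 93.6% in the control marrow-, relapse marrow- and relapse spleen-labelled libraries thinned to 1000 UMIs. The mixing fraction gave population 2 shares of 1.26%, 0.572%, 32.9% and 28.2%. Neutrophil-like cells were 5.15%, 10.7%, 7.26% and 27.3% with 500 mouse genes, and 21.7%, 6.91% and 34.9% in the control spleen-, relapse marrow- and relapse spleen-labelled libraries with the 95% limit. The control marrow-labelled share stayed within its interval of 7.02 to 8.11 with that limit, so the order of the marrow-labelled arms turned.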

Other observations

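In the spleen-labelled against the marrow-labelled control library, MHC class II genes had a median log2 ratio of 0.53 (99.97th percentile) over 5 members at a summed 8.07 against 4.18 CPM, interferon-stimulated genes 0.20 (99.8th), MHC class I genes -0.01, p53 targets 0.13, hypoxia-response genes 0.25 (99.83rd), glycolysis genes 0.12 (99.28th), oxidative phosphorylation genes -0.11, cytosolic ribosomal proteins 0.09 (100th), MYC targets -0.03 and ABC drug transporters 0.19. Adhesion and homing receptors stood at -0.09, cytokine receptor genes at 0.03, autophagy genes at 0.12, NF-kB genes at -0.03 and immediate early genes at -0.00048. Between arms, adhesion and homing receptors were higher in the marrow-labelled relapse library (6 of 21 members 1.5-fold, median 0.24), with CD44 at 33.4 against 19.3 CPM, but within population 1 only 1 of 21 was (0.10). NF-kB and TNF response genes were 1.5-fold higher in 7 of 17 members in the marrow-labelled relapse library (0.22) and in 4 of 18 in the spleen-labelled one (0.28), whose summed level was lower at 1270 against 1547 CPM. Within population 1 these counts were 3 of 17 (0.03) and 0 of 17 (0.12). HES4, a NOTCH-related factor, was at 22.0 against 1.302 and 14.2 against 0.425 CPM.

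Population 2 differed from population 1 in further lists. NF-kB and TNF response genes were higher in 11 of 18 members (median 0.84), p53 targets in 11 of 21 (0.78), adhesion and homing receptors in 10 of 21 (0.35) and cytokine receptor and JAK-STAT genes in 9 of 20 (0.24), while 7 of 28 MYC targets were lower (-0.41). Pancreatic enzyme genes that had not been looked at before stood 4.21 (2.90 to 6.35) times higher in the marrow-labelled than the spleen-labelled control library and 31.2 (22.7 to 44.2) times higher in the relapse arm. Cela1 gave 25 of 28 and 31 of 38 spleen-labelled UMIs, and without it the ratios were 26.35 (8.99 to 128) and 129.2 (62.6 to 322).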
